A study of Oryza sativa Japonica Group and Oryza sativa Indica Group and Oryza sativa Indica Group x Oryza sativa Japonica Group with 9 samples.

How the data were processed

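The series measured polyadenylated RNA in shoots of 14-day-old rice seedlings. It holds 9 RNA-seq libraries in 3 groups of 3: the cultivar C92, the cultivar MH63 and their F1 hybrid. The labels give C92 as japonica rice, MH63 as indica rice and F1 as a cross of both; MH63 stands for Minghui 63, a restorer line used in hybrid rice breeding. Seedlings stood in water in a growth chamber under 16 h of light at 100 µmol per square metre per second and 8 h of darkness, at 28 °C throughout. Per the labels' protocols, RNA was extracted with a plant column kit and treated with DNase, cDNA was primed with random hexamers and fragmented by nebulization, and libraries followed a standard Illumina protocol. Strand is not stated, so values of genes that overlap on opposite strands are uncertain. Protein measurements named in the series title were not analysed here.

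Per the submitters' processing notes, reads were aligned with HISAT2 2.0.5. The genome build, the annotation and the program that computed expression are not given in the sources used here. The values the authors deposited are FPKM (fragments scaled to transcript length and to the mapped fragments of the library), with 1 value per locus and library, 2 decimals and no header. Each library lists the same 55783 loci. FPKM already divides by locus length and library size, so no count model was used.

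Total read numbers are not given. Relative depth was read from the low values, because 1 fragment at a locus of fixed length is worth less FPKM in a deeper library. For each pair of libraries, the most frequent ratio of values between 0.2 and 1.5 was taken, counting ratios within 0.015 on the log2 scale, and ratios chained over 3 libraries closed to within 0.014. No confidence interval for counting error can be given without the read numbers.

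The files pair no locus ID with a gene name. The gene table used here (RefSeq, assembly ASM3414082v1) holds 0 of the 55783 locus IDs and gives no gene descriptions. Genes are therefore printed by locus ID only, with at most 2 IDs higher and 2 lower in each comparison. These are the loci with the largest fold changes among called loci whose libraries do not overlap between the groups and whose higher group averages at least 10 FPKM; against the mid-parent, every F1 library had to lie on one side of it. The chromosome of a locus is the number within its ID, and neighbours are neighbours in ID order. Of the gene lists fixed before the data were examined, 32 defined by words in gene descriptions could not be formed. The other 6 were lists of 61 locus IDs written from general knowledge of rice genes: loci that differ between the rice subspecies, clock and flowering genes, phytoalexin clusters, root markers, meristem markers and reference genes. No table used here ties these IDs to gene names, so membership was checked by place alone: the table places a gene of the intended symbol at a like position for 44 loci and holds no such symbol for 14. The other 3 loci were left out because the table places the gene elsewhere (over 0.03 of the chromosome length away, or on another chromosome). Members are not named. Some loci stand in both the subspecies list and the clock and flowering list, so the counts of these lists are not separate.

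Comparisons used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with all 9 libraries in 1 fit, a mean for each group, an intensity trend in the variance prior and no further covariate. Loci with FPKM of at least 1 in at least 3 libraries were tested, 21447 in all. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p below 0.05; a second count also required a change of at least 2-fold. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. F1 was set against both parents and against the mid-parent, taken as the log2 of the arithmetic mean of the parents' fitted levels, with the error propagated by the delta method from the same limma fit. Classes of F1 expression combine the calls of the pairwise comparisons; because both share the F1 libraries, overlaps are printed beside those of 100 simulated data sets with no group difference and beside the product expected of independent lists. Lists with at least 5 tested members were tested as in limma's camera with a preset correlation of 0.01 between genes, and again with an estimated correlation. This test finds a shift of the members in a common direction and can miss members that differ both ways. When the members of the subspecies list were shifted 2-fold in simulated data, 1 other list was called as well.

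Single-parent genes had FPKM of at least 1 in all 3 libraries of one parent and at most 0.1 in all 3 of the other, over all loci in the files. Their F1 level was divided by the mean of the expressing parent. The position of F1 between the parents is the F1 mean minus the MH63 mean, divided by the C92 mean minus the MH63 mean, in FPKM, so that 0.5 is the mid-parent. Medians carry intervals from 1000 bootstraps over genes, which describe the spread over genes and not over plants. Windows of 50 tested loci in ID order were laid along each chromosome; the last of a chromosome takes the remainder.

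The methods were tested on simulated data with the spread of the real libraries. The noise was normal, took its variances from the limma fit and was drawn independently for each gene and library. Deviations shared by libraries were thus left out, so the simulated counts describe the methods under their own model and cannot vouch for the real counts. Of 100 genes changed 2-fold, 81 were recovered for C92 versus MH63, 88 for F1 versus C92, 84 for F1 versus MH63 and 91 for F1 versus the mid-parent, with 10, 9, 9 and 7 false calls among 21447 genes. Of 100 genes changed 4-fold, 98, 97, 97 and 99 were recovered in the same order. A simulated hybrid at the exact arithmetic mean of its parents gave 0 calls against the arithmetic mid-parent and 510 against a mid-parent averaged on the log scale, over 21447 genes.

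The groups, the comparisons, the rule for printed loci, the 6 lists and most alternatives were fixed before the data were examined. Each pairwise comparison was recomputed under 20 alternatives: other pseudocounts (0.1 and 0.01), no expression filter or a stricter one (a mean FPKM of at least 5), other scalings (TPM, median ratio and quantile), the replicate number as a block, robust variance moderation, a fit of the 2 groups compared alone, each library left out in turn, and F1 libraries 1 and 2 left out together. That last one, and a mid-parent weighted by the parental share fitted on single-parent genes, were added after the data had been seen. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.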

Results

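Gene expression was measured in shoots of the japonica rice cultivar C92, the indica cultivar MH63 and their F1 hybrid, with 3 libraries for each. The series asks how expression patterns differ between rice lines; the comparisons here are between the parents and between the hybrid and each parent. The replicates are described as biological, with no word on how plants were divided among them, so p-values measure the spread between these samples. FPKM values summed to between 602005 and 623806 in each library. The number of loci above 0 was 31709, 31772 and 32198 in the C92 libraries, 30440, 31343 and 31225 in MH63, and 32611, 33131 and 33329 in F1. Of the 55783 loci, 11443 were listed at 0 in every library. Depth relative to C92 library 1 was 1.03 and 1.15 in the other C92 libraries, 0.955, 1.09 and 1.07 in MH63, and 1.01, 1.24 and 1.18 in F1. The 10 most abundant loci took between 7.05% and 8.52% of the FPKM sum.

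Libraries of a group resembled each other more than those of any other group. Pearson correlations across tested genes, which are not independent replicates, were 0.977 to 0.990 within groups, 0.868 to 0.887 between C92 and MH63, 0.929 to 0.964 between C92 and F1, and 0.918 to 0.938 between MH63 and F1. The first principal component held 64.9% of the variance and separated the parents, with mean scores of -57.3 for C92 and 65.3 for MH63. On this component the F1 libraries lay between them, at -9.89, -15.8 and 1.68 for libraries 1, 2 and 3. The second component, with 15.5% of the variance, set F1 apart from both parents. There, F1 libraries 1, 2 and 3 scored -25.5, -29.6 and -46.1, against 9.60 to 25.7 in the parents. On the first component, F1 libraries 1 and 2 stood on the C92 side of library 3. Values by library or with these 2 left out are printed beside the main F1 results.

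**Figure D1:**
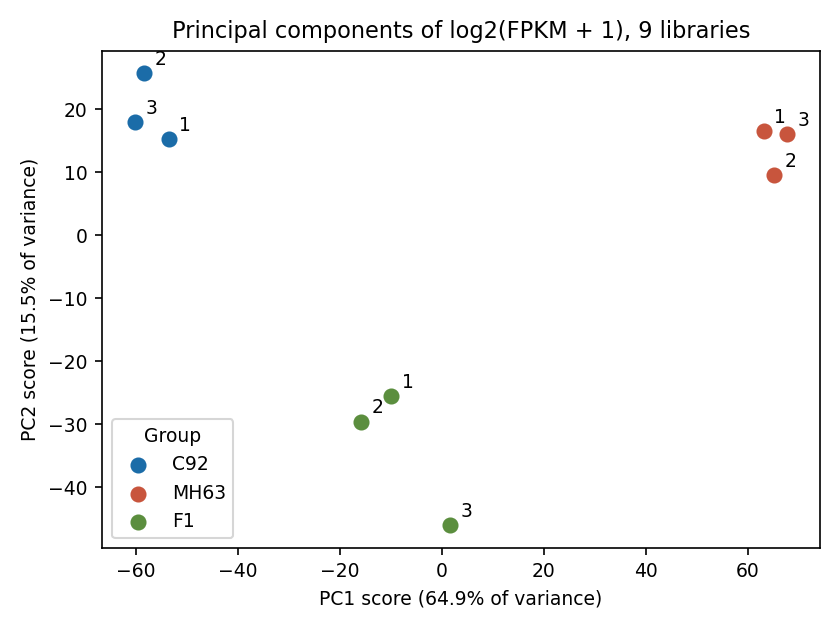
Scores of the 9 libraries on the first (x axis, 64.9% of variance) and second (y axis, 15.5%) principal components of log2(FPKM + 1), coloured by group and numbered by replicate. C92 and MH63 lie at opposite ends of the first component, and F1 library 3, at 1.68, lies nearer to MH63 than F1 libraries 1 and 2, at -9.89 and -15.8. On the second component F1 lies apart from both parents, from -25.5 in library 1 to -46.1 in library 3.

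The parents were compared to find how far the expression of the lines differs. Genes higher in C92 outnumbered genes higher in MH63: 4119 were higher and 3194 lower in C92, together 7313 of 21447 tested genes (34.1%). At 2-fold or more, 1386 genes were higher in C92 and 945 in MH63. The largest differences were close to presence against absence. LOC_Os10g11889 averaged 708 ± 39.3 FPKM in C92 and 0.183 ± 0.236 in MH63 (SD, n = 3), a log2 fold change of 9.25 (SE 0.14, limma adjusted p = 2.6e-10), and F1 held 548 ± 50.9. LOC_Os01g32270 averaged 566 ± 76.5 FPKM in C92, 0.200 ± 0.0794 in MH63 and 434 ± 0.522 in F1, with a log2 fold change of 8.88 (SE 0.10, adjusted p = 1.67e-10). In the other direction, LOC_Os08g31219 averaged 0.673 ± 0.0907 FPKM in C92, 124 ± 15 in MH63 and 30.2 ± 5.22 in F1, with a log2 fold change of -6.22 (SE 0.13, adjusted p = 1.41e-09). LOC_Os06g05440 averaged 0.0567 ± 0.0551 FPKM in C92, 76.9 ± 26.3 in MH63 and 27.0 ± 11.4 in F1, with a log2 fold change of -6.15 (SE 0.33, adjusted p = 4.82e-07). At an unadjusted p below 0.05, 9507 genes passed. The excess of genes higher in C92 depended on the scaling. After quantile normalization, 3516 genes were higher and 3748 lower in C92, while at 2-fold or more 1159 were higher and 1039 lower. The reference used for alignment is not given, so poorer matching of a parent's reads cannot be told apart from lower expression.

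The share of genes called between the parents was 34.1% over all tested genes. Of 13 tested clock and flowering loci, 1 was higher and 3 were lower in C92, and the counts were also 1 and 3 when adjusted over the list alone (list test adjusted p = 0.497). Of 12 tested loci that differ between the rice subspecies, 1 was higher and 1 lower, and 0 were called when adjusted over the list alone (adjusted p = 0.908). Of 5 reference genes, meant as genes of steady expression, 1 was higher and 1 lower in C92, also when adjusted over the list alone (adjusted p = 0.908). With an estimated correlation, the adjusted p was 0.921 for each of the 3 lists. Too few members were tested for a list test in the other 3: of 3 phytoalexin cluster loci 1 was lower in C92, of 3 root markers 1 was higher and 1 lower, and of 2 meristem markers 0 were called.

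Genes that differed between the parents were not spread evenly over the genome. The share of tested genes called ranged from 30.2% on chromosome 5 to 41.2% on chromosome 11. In windows of 50 neighbouring tested loci, the share called at 2-fold or more reached 50% in a window of chromosome 10, from LOC_Os10g03570 to LOC_Os10g05490, and 50% in a window of chromosome 12, from LOC_Os12g25200 to LOC_Os12g29330. A window of chromosome 4, from LOC_Os04g11195 to LOC_Os04g14304, reached 48%. Over all windows the share was 10.9%. These 3 windows are named for their values, after those had been seen.

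**Figure D2:**
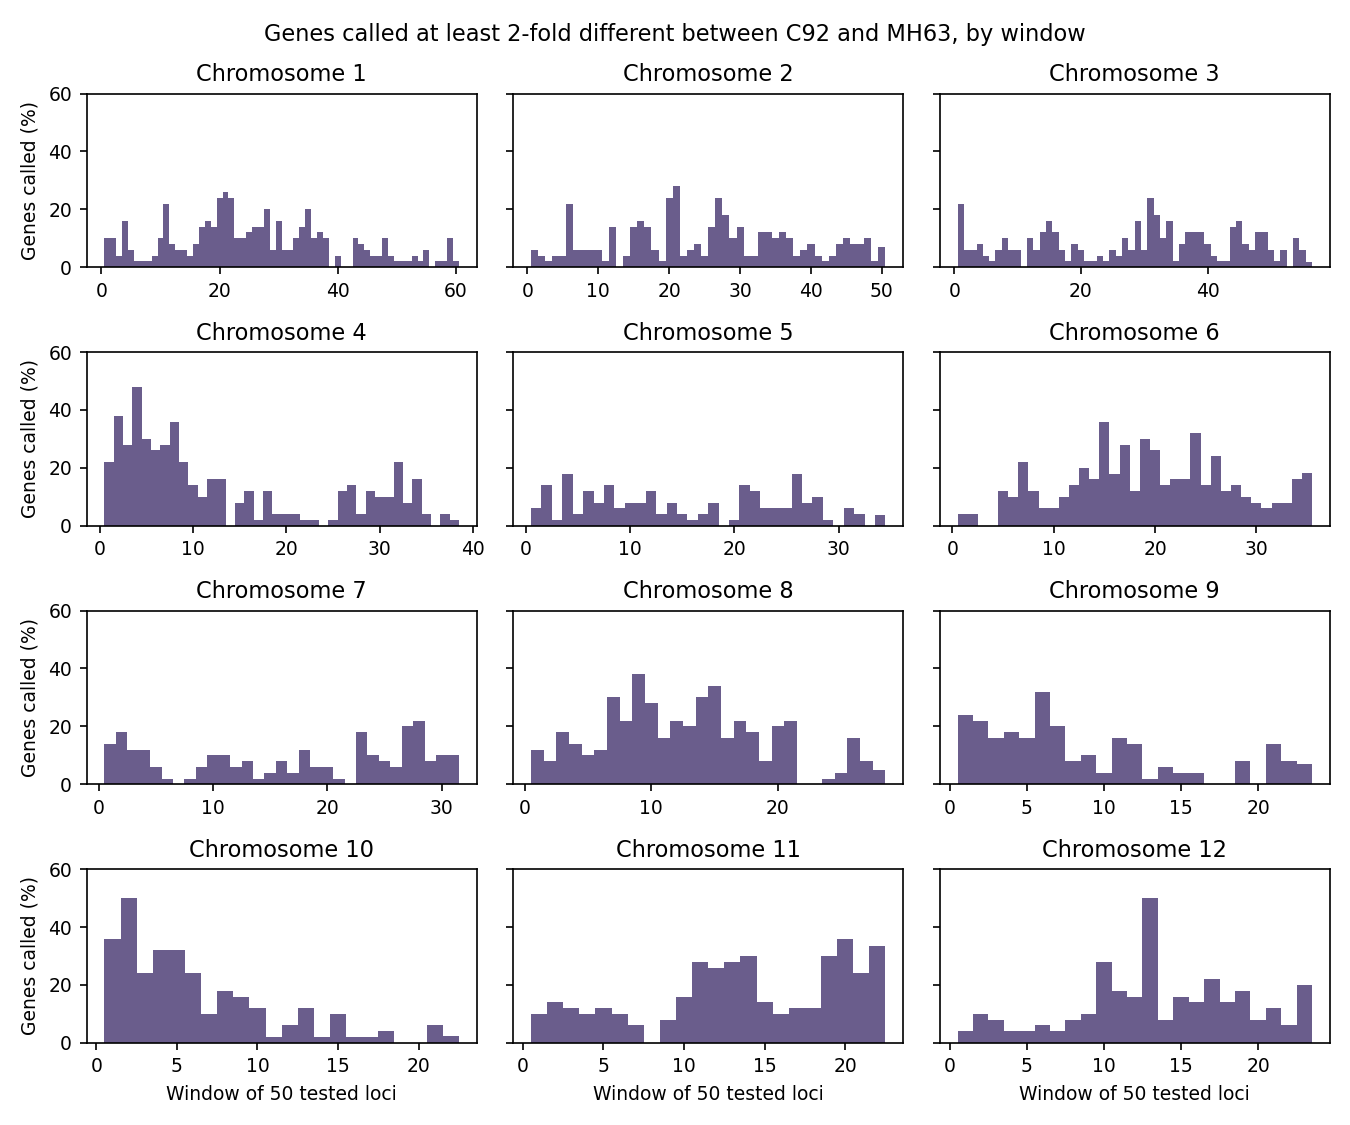
Share of tested genes called at least 2-fold different between C92 and MH63 (y axis, percent) in consecutive windows of 50 tested loci (x axis, window number in locus ID order), for each of the 12 chromosomes. The highest bars reach 50%, on chromosomes 10 and 12, against 10.9% over all windows.

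Some genes were expressed in a single parent. Above the limits, 515 genes were expressed only in C92 and 240 only in MH63. Chromosome 8 held 83 of the C92-only genes and 21 of the MH63-only genes, and chromosome 7 held 15 and 10. In F1, 511 of the 515 C92-only genes and 236 of the 240 MH63-only genes reached FPKM 0.1 in all 3 libraries. An F1 plant carries 1 copy from each parent, so equal activity of each copy in parent and hybrid would give a ratio of 0.5 to the expressing parent. The median ratio was 0.551 (bootstrap interval 0.535 to 0.565) for C92-only genes and 0.406 (0.389 to 0.424) for MH63-only genes. Taken by library, the ratios were 0.581, 0.560 and 0.479 for C92-only genes and 0.390, 0.334 and 0.486 for MH63-only genes, in F1 libraries 1, 2 and 3. The gap between the gene classes was therefore seen in libraries 1 and 2 and not in library 3.

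**Figure D3:**
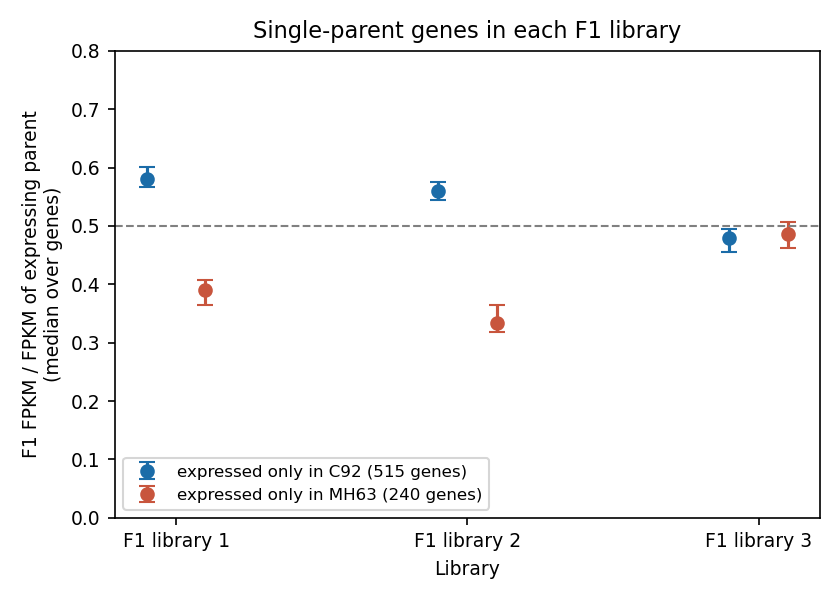
Median ratio of F1 FPKM to the FPKM of the expressing parent (y axis) in each F1 library (x axis), for 515 genes expressed only in C92 and 240 expressed only in MH63. Lines are bootstrap intervals over genes and the dashed line marks 0.5; the classes stand apart in libraries 1 and 2 (0.581 against 0.390 and 0.560 against 0.334) and overlap in library 3 (0.479 against 0.486).

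F1 was compared with C92 to find which genes departed from that parent in the hybrid. In F1, 2273 genes rose and 2934 fell against C92, together 5207 genes (24.3%). At 2-fold or more, 482 rose and 460 fell, and which side was larger depended on the libraries and settings used. LOC_Os03g45220 was listed at 0 in all 3 C92 libraries and averaged 29.2 ± 3.68 FPKM in F1 and 66.6 ± 4.93 in MH63 (SD, n = 3, limma adjusted p = 4.97e-08 for F1 against C92). LOC_Os03g22720, also listed at 0 in C92, averaged 25 ± 3.48 FPKM in F1 and 47.6 ± 6.42 in MH63 (adjusted p = 1.4e-07). LOC_Os11g35930 averaged 48.5 ± 26.9 FPKM in C92 and 4.31 ± 1.44 in F1, below the 20 ± 5.07 of MH63, with a log2 fold change of -3.13 (SE 0.35, adjusted p = 0.00049). LOC_Os10g05930 averaged 17.1 ± 7.05 FPKM in C92, 1.69 ± 0.790 in F1 and 0.240 ± 0.0700 in MH63, with a log2 fold change of -2.72 (SE 0.29, adjusted p = 0.000433).

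Against C92, 8152 genes passed at an unadjusted p below 0.05. The number called fell to 3174 without C92 library 2, to 3301 without C92 library 3 and to 3034 without F1 library 3. With F1 libraries 1 and 2 left out, 1540 genes rose and 2695 fell. At 2-fold or more, 603 then rose and 1123 fell. Counts at 2-fold or more were 426 risen and 253 fallen without F1 library 3, 484 and 625 without C92 library 1, 509 and 600 without F1 library 1, and 488 and 621 without F1 library 2. They were 458 and 491 with median-ratio scaling, 462 and 518 after quantile normalization, and 240 and 324 at a mean FPKM of at least 5. Among the planned lists, 0 of 13 clock and flowering loci were called, also over the list alone, and 1 of 12 subspecies loci was lower, with 0 adjusted over the list alone. Of 5 reference genes, 1 was lower, also adjusted over the list alone. The list tests gave an adjusted p of 0.737 for each of these 3. Of 3 phytoalexin cluster loci 1 was higher, of 3 root markers 1 was higher, and of 2 meristem markers 0 were called.

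F1 was compared with MH63 in the same way. In F1, 2474 genes rose and 1583 fell against MH63, together 4057 genes (18.9%). At 2-fold or more, 910 rose and 332 fell. After quantile normalization the counts were 2037 and 2000, and at 2-fold or more 734 and 468. Here too, poorer matching of MH63 reads to the reference cannot be told apart from lower expression in MH63. LOC_Os10g11889 and LOC_Os01g32270, nearly absent from MH63, had the largest rises, with log2 fold changes of 8.87 (SE 0.14, limma adjusted p = 5.88e-10) and 8.51 (SE 0.10, adjusted p = 2.49e-10). LOC_Os12g43390 was listed at 0 in C92 and averaged 40.4 ± 24.2 FPKM in MH63 and 0.95 ± 0.754 in F1 (SD, n = 3), with a log2 fold change of -4.26 (SE 0.44, adjusted p = 0.000133). LOC_Os08g10304 averaged 0.417 ± 0.0586 FPKM in C92, 37.5 ± 15.6 in MH63 and 1.14 ± 0.191 in F1, with a log2 fold change of -4.10 (SE 0.23, adjusted p = 1.51e-06).

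Against MH63, 6967 genes passed at an unadjusted p below 0.05. With F1 libraries 1 and 2 left out, 1125 genes rose and 861 fell, together 1986. Without MH63 library 1, 1868 rose and 974 fell. Of 13 clock and flowering loci, 1 was higher and 1 lower in F1, against 1 and 2 when adjusted over the list alone. Of 12 subspecies loci 1 was lower, with 0 adjusted over the list alone, and of 5 reference genes 0 were called on either count. The list tests gave an adjusted p of 0.535 for each of the 3. Of 3 phytoalexin cluster loci 1 was lower, of 3 root markers 1 was higher and 1 lower, and of 2 meristem markers 0 were called.

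Combining both comparisons sorted genes into classes of F1 expression. In F1, 284 genes were above both parents and 292 below both, while 1305 differed from both and lay between them. A further 3326 genes differed from C92 only and 2176 from MH63 only, and 14064 differed from neither. At 2-fold or more, 28 genes were above both parents, 29 below both and 243 between them. Simulated data with no group difference, which share the F1 libraries in the same way, gave a mean of 19.1 genes above, 19.0 below and 0.24 between. They do not cover genes in which F1 truly differs from 1 parent. For such a gene, a chance call against the other parent alone would change its class, so these means may understate chance. Simulated genes were counted at the highest unadjusted p among the genes called in the real data, not at an adjusted p of their own. Independent lists of the observed sizes would overlap in 262, 217 and 506 genes. The 3 F1 libraries were not divided between the comparisons, since one side would keep 1 library. Part of the excess of genes above and below both parents may come from the shared libraries. Among genes with no group difference, chance values of shared libraries push both comparisons the same way and rarely place a gene between the parents.

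The counts above both parents, below both and different from C92 only moved by more than 1.5 times when some single libraries were left out. Genes above both parents numbered 163 without C92 library 2, 176 without C92 library 3, 171 without MH63 library 1, 167 without F1 library 2 and 143 without F1 library 3. Genes below both numbered 192 without C92 library 2, 180 without C92 library 3, 124 without MH63 library 1, 182 without MH63 library 2 and 114 without F1 library 3. Genes that differed from C92 only numbered 1764 without C92 library 2, 1960 without C92 library 3 and 1777 without F1 library 3. With F1 libraries 1 and 2 left out, 120 genes were above both parents, 429 below both and 642 between them, and 795 differed from MH63 only.

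F1 was also compared with the mid-parent, the level that 1 copy from each parent at its parental activity would give. In F1, 721 genes rose and 1196 fell against it, together 1917 genes (8.94%). With the mid-parent averaged on the log scale, 1496 rose and 1103 fell. At 2-fold or more, 86 rose and 139 fell against the arithmetic mid-parent, and 314 and 91 against the log-scale one. LOC_Os08g07080 averaged 37.7 ± 13.4 FPKM in F1, 2.47 ± 1.05 in C92 and 2.59 ± 3.38 in MH63 (SD, n = 3), with a log2 fold change of 3.62 over the mid-parent (SE 0.48, limma adjusted p = 0.00558). LOC_Os09g31031 averaged 42.0 ± 29.7 FPKM in F1, 6.60 ± 2.77 in C92 and 4.15 ± 1.69 in MH63, with a log2 fold change of 2.47 (SE 0.52, adjusted p = 0.023). Its call was lost without C92 library 3 (log2 fold change 2.49, adjusted p = 0.0504), F1 library 2 (2.23, 0.0739) or F1 library 3 (1.94, 0.0879). The largest falls were those of LOC_Os12g43390, with a log2 fold change of -3.30 (SE 0.44, adjusted p = 0.00548), and LOC_Os08g10304, with -3.16 (SE 0.22, adjusted p = 0.000568). With F1 libraries 1 and 2 left out, the call of LOC_Os12g43390 was lost (adjusted p = 0.0569). Both were expressed in MH63 and nearly silent in F1 and C92.

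**Figure D4:**
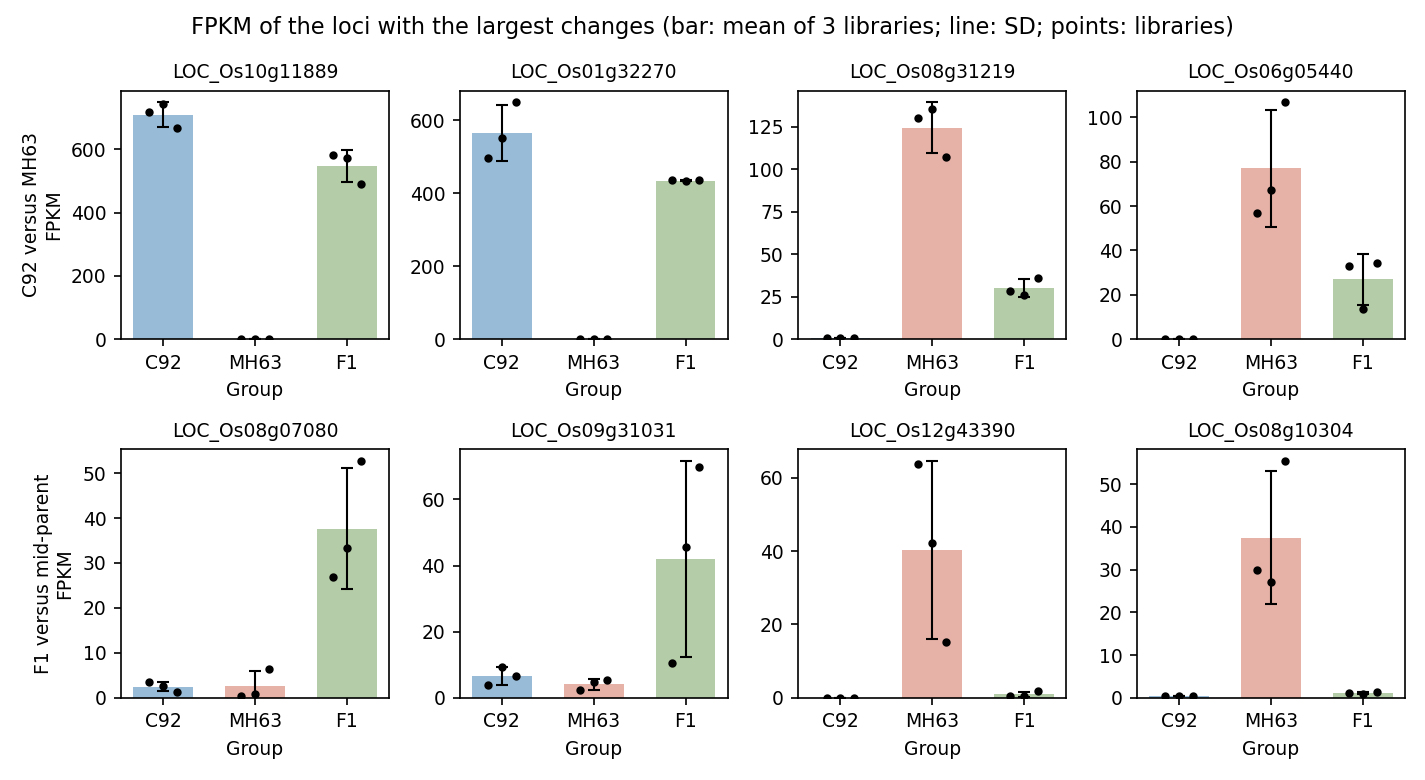
FPKM (y axes, from 0) in C92, MH63 and F1 of the loci with the largest changes between the parents (top row) and between F1 and the mid-parent (bottom row); bars are means of 3 libraries, lines SD and points libraries. LOC_Os12g43390 and LOC_Os08g10304 averaged 40.4 and 37.5 FPKM in MH63 against 0.95 and 1.14 in F1.

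Against the mid-parent, 5897 genes passed at an unadjusted p below 0.05. Of the 1917 genes called, 970 also differed between the parents: 415 of these lay on the C92 side of the mid-parent and 555 on the MH63 side. With the log-scale mid-parent these were 824 and 678, without C92 library 2 they were 240 and 212, without C92 library 3 they were 233 and 225, and without F1 library 3 they were 201 and 142. The split widened to 326 and 674 without C92 library 1, and to 121 and 531 with F1 libraries 1 and 2 left out. The number called was 914 without C92 library 2, 991 without C92 library 3 and 980 without MH63 library 1. It was 1022 without F1 library 2 and 505 without F1 library 3. At 2-fold or more it was 123 without F1 library 3. When single libraries were left out, 24.8% (F1 library 3) to 77.4% (C92 library 1) of the 1917 genes were still called. With no filter 40% were, and with the other scalings 94.3% to 96.1%. With F1 libraries 1 and 2 left out, 191 genes rose and 929 fell. Of 13 clock and flowering loci 0 were called on either count, and of 12 subspecies loci 1 was lower, also adjusted over the list alone. Of 5 reference genes 1 was lower, against 1 higher and 1 lower when adjusted over the list alone. The list tests gave an adjusted p of 0.702 for each of the 3. Of 3 phytoalexin cluster loci, 3 root markers and 2 meristem markers, 0 were called.

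The position of F1 between the parents was measured on the 2331 genes called at 2-fold or more between them. The median position was 0.563 (bootstrap interval 0.553 to 0.570), where 0 is the MH63 level and 1 the C92 level. It was 0.534 for the 1386 genes higher in C92 and 0.603 for the 945 genes higher in MH63. By library it was 0.584 in F1 library 1, 0.607 in library 2 and 0.479 in library 3.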

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

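Leaving out F1 libraries 1 and 2 together and weighting the mid-parent were tests chosen after the data had been seen; the other alternatives were planned. No printed locus changed direction; the larger side of all genes called between the parents turned only under quantile normalization. Alternatives left 288 values within 1.5 times or their spread, list tests at 0 included, and moved 59 further. This tally ignores gene identity. For printed loci, 319 kept the call and 5 lost it. The lost calls, all against the mid-parent, were those of LOC_Os09g31031 without C92 library 3, F1 library 2 or F1 library 3 and with no filter (adjusted p over its alternatives 0.00559 to 0.0879), and of LOC_Os12g43390 with F1 libraries 1 and 2 left out (over its alternatives 0.00106 to 0.0569). Requiring a mean FPKM of at least 5, which tests fewer genes, gave 4538 called genes for C92 versus MH63 (1059 at 2-fold or more), 3359 (564) for F1 versus C92 and 2289 (613) for F1 versus MH63, with 187 genes above both parents, 588 between them and 1293 that differed from MH63 only. With no filter, 912 genes were called against the mid-parent and 145 were below both parents. Smaller pseudocounts raised the counts at 2-fold or more: at 0.1 to 1641 (F1 versus C92), 1867 (F1 versus MH63) and 380 (mid-parent), and at 0.01 to 1622 (F1 versus C92) and 353 (mid-parent), since they shrink low genes' fold changes less. Quantile normalization put 459 genes below both parents; the cause was not tested. The log-scale mid-parent, which lies below the arithmetic one where the parents differ, gave 405 genes at 2-fold or more. No scaling moved the median of all genes by more than 0.0609 on the log2 scale. Classes built on calls of at least 2-fold held 28 genes above both parents, 29 below both, 243 between, 942 that differed from MH63 only and 642 from C92 only. A silent parent listed at exactly 0 left 319 C92-only and 148 MH63-only genes, and an expressing parent at FPKM 5 or more left 199 and 83. None of the 12 list tests was called under any alternative run (camera-style test; lowest unadjusted p with all libraries 0.166, and 0.318 with an estimated correlation).

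With F1 libraries 1 and 2 left out, F1 rests on 1 library, which is assumed to vary like the other groups. There were then 1726 genes at 2-fold or more against C92, 1986 called against MH63, and 1120 against the mid-parent (488 at 2-fold or more); 120 were above both parents, 429 below both, 642 between and 795 differed from MH63 only. The position of F1 was 0.479, and its ratio to the expressing parent was 0.479 for C92-only and 0.486 for MH63-only genes. Weighting C92 by its fitted share of 0.575 gave 1990 genes against the mid-parent, 278 on the C92 side and 750 on the MH63 side among genes that differed between the parents.

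Leaving out each library in turn, which leaves fewer samples, gave 5466 to 7435 genes for C92 versus MH63 (2270 to 2486 at 2-fold or more), 3034 to 5585 for F1 versus C92 (679 to 1109), 2842 to 4088 for F1 versus MH63 (1147 to 1299) and 505 to 1827 for the mid-parent (123 to 278). The classes ranged from 143 to 240 above both parents, 114 to 317 below both, 985 to 1237 between, 1455 to 2553 that differed from MH63 only and 1764 to 3895 that differed from C92 only. The position ranged from 0.536 to 0.600, the ratios from 0.527 to 0.579 and from 0.369 to 0.438, C92-only genes from 515 to 552 and MH63-only genes from 240 to 264.

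The replicate numbers are shared by the groups but nothing ties a number to a day or batch. Deviations of same-numbered libraries from their group means correlated at -0.432 to 0.343 over 9 pairs, and 2 of 9 libraries correlated best with their own number, so the numbers were not taken as pairs; libraries of other numbers reached 0.415. With the replicate block, 6645 genes were called for C92 versus MH63, 4584 for F1 versus C92, 3479 for F1 versus MH63 and 1316 for the mid-parent.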

Other observations

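Of the tests in this part, the share of single-parent genes listed at exactly 0, the share of called genes at a distance and the reassignment of deviations from an additive hybrid were set out before their results were seen; all others, the other groupings of the libraries included, were chosen only after the result was seen.

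F1 libraries 1 and 2 lay nearer to C92 than F1 library 3 on single-parent genes, with a ratio for C92-only genes above that for MH63-only genes by 0.191 and 0.226, against -0.00703 in library 3; the first 2 leaned to C92 on 12 of 12 chromosomes and library 3 on 4. A scaling error would move both gene classes the same way, but in library 1 the C92-only ratio lay 0.102 above that of library 3 and the MH63-only ratio was shifted by -0.0966 (interval -0.121 to -0.0714). Holding the parent library in the ratio out of the choice of genes left the leans of libraries 1 and 3 apart by 0.211, which decides nothing, since the F1 libraries share the gene choice and the parental levels. If library 3 is taken as pure F1, admixed C92 material is a candidate explanation for library 1, where the gain on C92-only genes asks for 19.6% and the loss on MH63-only genes for 19.9% (difference -0.287 points, interval -5.34 to 5.76); alone it is argued against in library 2, where the shares were 15.4% and 31.4% (difference -16.0 points, interval -20.3 to -9.41; -21.4 after median-ratio scaling). The design names no biological difference among the F1 libraries, so none was tested, and a wrong choice of library 3 as the pure one stays open.

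More genes were expressed only in C92 (515) than only in MH63 (240). Lower depth of the MH63 libraries is argued against: in pairs of libraries of which MH63 was the deeper, the lowest ratio of C92-only to MH63-only genes was 1.52. Loci missing from MH63, or whose MH63 reads were not matched to the reference used, would be listed at exactly 0 more often, but 61.9% of C92-only and 61.7% of MH63-only genes were (difference 0.275 points, interval -7.44 to 8.27), so this explanation and a true difference in expression between the parents cannot be told apart; the interval reaches both sides of 0 and the reference used for alignment is not given here. The difference between the parents, which the design names, stays open as untested.

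Genes called at 2-fold or more between the parents clustered along the chromosomes. Random placement is argued against: the SD over 422 windows of the percent called was 8.85, against a highest value of 5.10 (mean 4.49) in 1000 permutations among genes of like expression. Tandem copies or overlapping neighbours alone are argued against as well, since 15.2% of tested loci that lay 20 to 49 loci from a called gene were called themselves, against a highest value of 11.4% in the permutations and 10.9% over all tested loci. Windows rich in single-parent genes were also rich in other genes called at 2-fold or more. The Spearman rho across windows, which are not independent, was 0.518, against a highest value of 0.446 in 400 circular shifts. Both gene sets come from the same comparison of the same libraries, and the shifts did not hold expression level fixed. The rho is therefore no separate support for the hypothesis that the parents differ more in some blocks of the genome than in others. Sequence differences between the parents were not analysed here, and whether such blocks act on expression or on the matching of reads to the reference stays open.

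Other groupings of the libraries were counted for each comparison. Each pairwise comparison has 10 splits of 6 libraries into 3 and 3, of which 1, the real one, gave as many genes. The real counts were 7313 for C92 versus MH63, 5207 for F1 versus C92 and 4057 for F1 versus MH63 (highest other 0 in each). Mixed splits carry the difference between the groups as spread, so their 0 calls say little. Besides, 10 splits are too few for a share under 0.05. Against the mid-parent, 1 of 100 groupings of the 9 libraries, the real one, gave as many genes (1917, highest other 748). That says little, since mixed groups carry the parental difference as spread and most call 0. When only the deviations from an additive hybrid were reassigned, 1 of 100 assignments, the real one, gave as many genes (1917, highest other 347). The parents' deviations average to 0 by construction, which favours the real assignment, so neither count decides on chance.

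Deviations from the group means were shared by libraries of different groups, mostly under different replicate numbers. C92 library 1, MH63 library 3 and F1 library 1 correlated at 0.415 (C92 with MH63), 0.364 (MH63 with F1) and 0.343 (C92 with F1), and C92 library 3, MH63 library 1 and F1 library 2 at 0.403, 0.264 and 0.167 in the same order. Placed together as F1, the first set gave 347 genes in the reassignment of deviations. The second set gave 92 or 0, depending on how the other libraries were assigned. Most other sets gave 0. The labels name no day or batch, these sets were picked for their values, and the source of the shared deviations was not tested.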
